A study of Homo sapiens with 8 samples.

How the data were processed

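The series holds 8 RNA sequencing libraries of DLD1 cells in 4 groups of 2: a control hairpin, whose genotype label is WT, or a hairpin against PPA2, each under normoxia or hypoxia for 12 hours. Per the labels, total RNA was extracted with Trizol and treated with DNase, poly(A) RNA was selected and libraries were made with a directional kit. Per the submitters' processing notes, reads were trimmed with cutadapt 1.18 and Trimmomatic 0.35, checked with FastQC and aligned to GRCh38 with HISAT2 2.1.0. The tool that counted reads and the gene annotation are not given in the sources used here.

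The normoxia values were deposited as RPKM by gene symbol for 60234 genes, per the file headers. The hypoxia values were deposited as FPKM by Ensembl identifier and symbol for 60612 genes, per the file headers. An annotated sheet of the hypoxia table held 19630 genes, with 0 values that differed, and supplied GRCh38 coordinates. A sheet of correlations was not used, and neither were 4 columns of samples that are not part of this series. As each table was normalized on its own, knockdown was tested only within a table. Genes were matched between tables by the 57069 symbols used once in each.

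The depth of the normoxia libraries was estimated from single-exon genes, whose RPKM must be whole multiples of the value of 1 read. At the estimates, 28004663, 35722660, 35735957 and 30725480 reads for control replicates 1 and 2 and knockdown replicates 1 and 2, 89.7%, 89.7%, 90.5% and 90.0% of such genes with up to 20 reads fell within 0.02 of a whole read. The value of 1 read was chosen so that most values were whole, so these shares are not an independent check. No depth estimate was made for the hypoxia table. Without counts, error was taken from the spread between replicates, and the median standard error of a log2 fold change was 0.08 under normoxia, 0.10 under hypoxia and 0.13 for their difference.

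Values were analysed as log2(value + 1), which understates the fold change of genes with low values. Where 1 group was listed at 0 in both libraries, the results give levels without a fold change, and the differences of MT-TY and MT-TC printed at the end depend on the pseudocount. Where a gene was listed at 0 in all normoxia libraries, the difference of responses equals its change under hypoxia. Genes with a mean of at least 1 over the fitted libraries were tested with limma 3.58.1 (linear model, moderated t with a mean-variance trend) in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method and genes called at an adjusted p under 0.05. Knockdown was compared with control in each table, and the difference of both responses was the interaction term of a fit of all 8 libraries. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Agreement of both responses was described by correlations across genes and by Fisher's exact test on the overlap of calls. Levels under hypoxia and normoxia were only described, against 10000 random lists matched on mean expression.

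Before the data were examined, 43 gene lists, the comparisons, the alternatives and a rule for named genes were fixed. The 40 lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, and again with a correlation estimated from the data. The version with an estimated correlation had only the residual degrees of freedom of the fit, 2 within each oxygen level and 4 for the difference. So few degrees of freedom left little room for any list to pass. A call lost there therefore does not show that correlated genes had produced it. The rule named PPA2 and PPA1, the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap, up to 4 members of each passing list and of the HIF, interferon, complex I and integrated stress response lists, the 5 largest interactions of each sign, and genes that check the oxygen labels. Members that went against their list, mitochondrial genome genes beyond the rule, chemokine genes and the largest changes among protein-coding genes were named after their values were seen. Some genes that the rule or a list would name are not reported here.

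The steps were tested on simulated data with known changes. At 1.5, 2 and 4-fold, 34.3%, 73.1% and 84.8% of changed genes were recovered for normoxia, 16.4%, 71.6% and 93.9% for hypoxia and 16.4%, 64.2% and 93.9% for the difference. False calls made up 2.29%, 4.72% and 7.94% of calls. The 1 shifted list was called each time and 0 of 39 other lists were. The simulated noise was independent between genes and few genes were changed. In the data, 34.2% to 58.4% of tested genes were called, and the estimated correlation reached 0.71 for cytosolic ribosomal proteins under hypoxia. The simulation therefore cannot show how often camera calls lists falsely in these data. Alternatives were other pseudocounts (0.1 and 0.01), filters, scalings and thresholds, a robust fit, a fit of all libraries, a replicate block, the fry list test and fits without each library in turn. Fits without mitochondrial genome genes, fits of protein-coding genes only, list tests after quantile normalization and list medians corrected for GC content and transcript length were added after results were seen.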

Results

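Messenger RNA was sequenced from DLD1, a human colorectal adenocarcinoma cell line, carrying either a control hairpin RNA (genotype label WT) or a hairpin against PPA2, the gene for mitochondrial inorganic pyrophosphatase, which splits pyrophosphate in the mitochondrial matrix. Cells of both kinds were kept for 12 hours under normoxia or under hypoxia, which gave 4 groups of 2 libraries, 8 libraries in all. The normoxia libraries came as reads scaled by gene length and library size (RPKM) for 60234 genes and the hypoxia libraries as fragments scaled in the same way (FPKM) for 60612 genes, in tables normalized separately. The steps between low RPKM values of single-exon genes placed the depth of the normoxia libraries at an estimated 28004663 and 35722660 reads for control replicates 1 and 2 and 35735957 and 30725480 reads for knockdown replicates 1 and 2. The depth of the hypoxia libraries is unknown. Across genes, replicates correlated at r = 0.995 (control) and 0.994 (knockdown) under normoxia and at 0.992 and 0.994 under hypoxia, against 0.979 to 0.982 and 0.930 to 0.934 between control and knockdown libraries. The median standard error of a log2 fold change was 0.08 under normoxia and 0.10 under hypoxia. The labels do not say whether replicates are separate cultures, so limma p-values measure only the spread between these samples, which may be technical. Camera p-values at the preset correlation set the genes of a list against other genes and treat genes as nearly independent. They overstate the evidence where genes of a list are correlated (estimated correlation up to 0.71) and do not measure replication between libraries.

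PPA2 itself fell at both oxygen levels, which checks the knockdown labels. The gene (ENSG00000138777) lies on the minus strand of chromosome 4, from 105369077 to 105474067 in GRCh38. Under normoxia it stood at 79.8 and 84.1 RPKM in the control libraries (81.9 ± 3.09, SD, n = 2) and at 5.88 and 5.74 RPKM in the knockdown libraries (5.81 ± 0.101, SD, n = 2). The log2 fold change was −3.61 ± 0.06 (SE), 12.2-fold, with a limma adjusted p of 4.12e-06. Under hypoxia it stood at 65.5 and 50.8 FPKM in the control libraries (58.2 ± 10.4, SD, n = 2) and at 9.85 and 9.0 FPKM in the knockdown libraries (9.42 ± 0.600, SD, n = 2), a log2 fold change of −2.49 ± 0.12 (SE), 5.64-fold, with a limma adjusted p of 3.01e-05. The fall of PPA2 was smaller under hypoxia by 1.11 ± 0.15 on the log2 scale (limma adjusted p = 0.00034). PPA1 (ENSG00000180817, chromosome 10), the cytosolic pyrophosphatase, fell from 322 to 264 RPKM under normoxia (−0.29 ± 0.06, limma adjusted p = 0.0109) and from 233 to 128 FPKM under hypoxia (−0.86 ± 0.07, limma adjusted p = 0.000103). Without control replicate 2 the normoxia value of PPA1 was −0.26 and its adjusted p 0.065. The fall of PPA1 was larger under hypoxia by −0.57 ± 0.09 on the log2 scale (limma adjusted p = 0.000651).

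**Figure D1:**
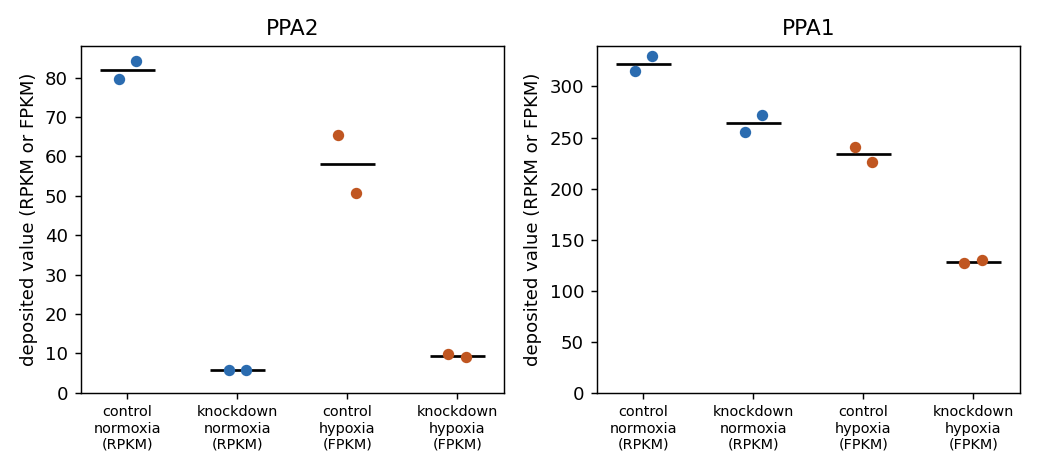
Deposited values of PPA2 and PPA1 in each of the 8 libraries (points, RPKM for normoxia in blue and FPKM for hypoxia in orange) with the mean of each group (black line). PPA2 lies between 50.8 and 84.1 in the control libraries and between 5.74 and 9.85 in the knockdown libraries, and RPKM and FPKM were normalized separately, so the oxygen levels are not on one scale.

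The comparison under normoxia asks what differs with the PPA2 hairpin without imposed hypoxia. The labels name no other hairpin against PPA2 and no rescue. At both oxygen levels, effects of the hairpin itself therefore cannot be told apart from loss of PPA2. Knockdown cells had lower transcripts of hypoxia-response, stress and sterol genes and higher transcripts of antigen presentation and interferon genes. None of these gene lists held with a correlation estimated from the data, a test whose 2 residual degrees of freedom left little room to pass. DDIT4, an inhibitor of mTORC1 signalling that stress and low oxygen induce, fell from 143 to 13.6 RPKM (log2 fold change −3.30 ± 0.08 SE, 9.87-fold, limma adjusted p = 2.33e-05). NDRG1, a hypoxia-induced gene linked to growth arrest and differentiation, fell from 86.4 to 16.8 RPKM (−2.29 ± 0.10, limma adjusted p = 0.00017). TXNIP, an arrestin-like protein that restrains glucose uptake and binds thioredoxin, rose from 8.33 to 42.5 RPKM (2.22 ± 0.06, 4.66-fold, limma adjusted p = 3.99e-05). HLA-B, a class I molecule that presents peptides to T cells, rose from 22.0 to 76.2 RPKM (1.75 ± 0.06, 3.35-fold, limma adjusted p = 5.88e-05).

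The other largest rises were those of the cytokine gene LTB (1.99 ± 0.11), the keratin-associated gene KRTAP3-1 (1.81 ± 0.11), the immunoproteasome subunit PSMB9 (1.80 ± 0.09), the secreted ligand WNT5A (1.76 ± 0.08), the protocadherin PCDH1 (1.69 ± 0.08), the matrix protein NPNT (1.58 ± 0.07), the transcript AC087793.1 (1.58 ± 0.15) and MIR635 (1.56 ± 0.27), a microRNA gene too short for a firm value in these libraries. The other largest falls were those of ANKRD37 (−2.03 ± 0.16), the transcription factor JUN (−1.88 ± 0.07), the stress cytokine GDF15, which went from 277 to 78.8 RPKM (−1.80 ± 0.11), the G protein subunit GNG5 (−1.76 ± 0.12), the vasodilator peptide gene ADM (−1.72 ± 0.09), the glycolytic enzyme PGK1, which went from 225 to 68.5 RPKM (−1.70 ± 0.05), and the repressor BHLHE40 (−1.69 ± 0.07). Limma adjusted p-values of these 15 genes lay between 3.99e-05 (PGK1) and 0.00725 (MIR635). In every gene called as changed and named for either knockdown comparison, both knockdown libraries lay on the same side of both control libraries. The rule required this of the largest rises and falls. It also held for 70.5% (normoxia) and 80.4% (hypoxia) of all tested genes, so it adds no separate evidence.

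Genes that HIF transcription factors induce in low oxygen fell together under normoxia. Of 27 tested, 20 fell and 2 rose (22 and 2 adjusted over the list alone), with a median log2 fold change of −0.85. DDIT4, NDRG1, ANKRD37 and ADM led the falls, and VEGFA, the angiogenic growth factor gene, went from 116 to 42.0 RPKM (−1.44). The risers were the oxidoreductase ERO1A (0.36) and the collagen hydroxylase P4HA2 (0.38). Of 20 glycolysis genes, 14 fell and none rose (15 and 0 adjusted over the list alone, median −0.38), among them PGK1, ALDOC (−1.44), HK2 (−1.14) and the glucose transporter SLC2A1 (−0.78). Targets of ATF4, the transcription factor of the integrated stress response, also fell. Of 24 tested, 17 fell and 2 rose (19 and 2 adjusted over the list alone, median −0.44), with DDIT4, GDF15, the amino acid transporter SLC7A5 (−1.03) and PPP1R15A (−0.95) lowest and ATF5 (0.39) and SESN2 (0.45) higher. Of 25 immediate early genes, which respond to growth signals within minutes, 15 fell and 2 rose (17 and 2 adjusted over the list alone, median −0.45), with JUN, EGR1 (−1.18), IER3 (−0.99) and ZFP36 (−0.93) lowest and DUSP4 (0.68) and BTG2 (0.86) higher. Of 18 heat shock genes, 12 fell and 2 rose (12 and 2 adjusted over the list alone, median −0.28), led by HSPA1B (−1.27), HSPA1A (−1.25), DNAJB1 (−0.93) and HSPH1 (−0.57), against DNAJB4 (0.26) and DNAJA1 (0.21). HSPA1A and HSPA1B are near-identical and can share reads, and some genes, such as DDIT4, stand in more than 1 of these lists. The camera adjusted p was 1.84e-13 for the HIF list, 4.51e-09 for glycolysis, 4.69e-11 for ATF4 targets, 2.17e-08 for immediate early genes and 4.15e-07 for heat shock genes. None of the 5 lists held with correlation taken from the data, at adjusted p = 0.263 to 0.3 with an estimated correlation. Heat shock genes had an estimated correlation of −0.044, below the preset 0.01, yet the unadjusted camera p went from 8.31e-08 to 0.0285. Correlated genes do not account for that loss, as the test had 2 residual degrees of freedom. Calls of some members against the trend rested on 1 library, with a limma adjusted p over 0.05 without control replicate 1 for ATF5 (0.125), DNAJA1 (0.214) and DNAJB4 (0.11), without control replicate 2 for DNAJA1 (0.0733) and DNAJB4 (0.129), without knockdown replicate 1 for ATF5 (0.102) and without knockdown replicate 2 for DNAJA1 (0.0585) and DNAJB4 (0.0738).

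**Figure D2:**
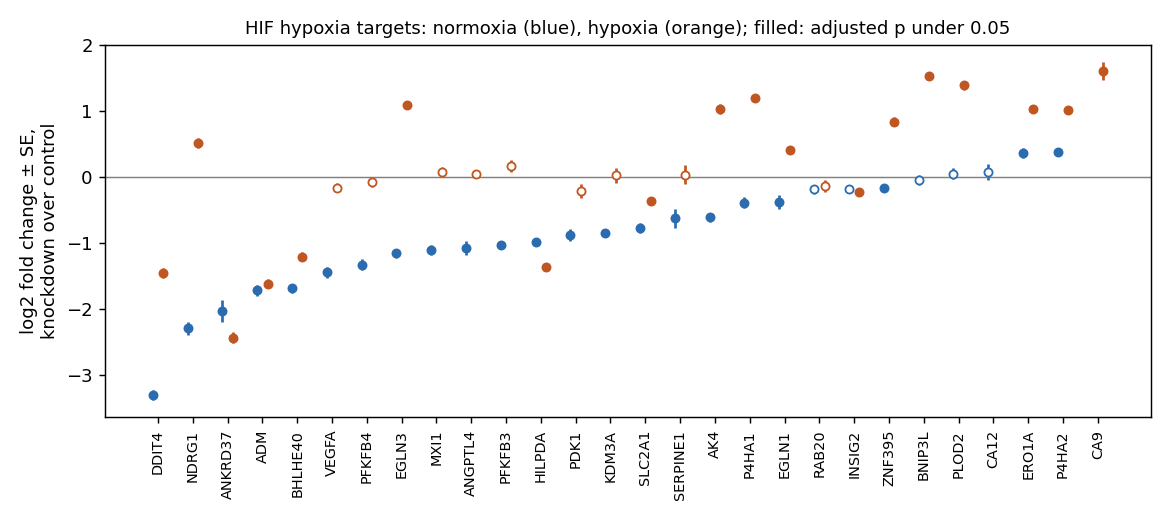
Log2 fold change (knockdown over control, log2 of value + 1, points) with its SE (bars, n = 2 libraries per group) of each tested HIF target, under normoxia in blue and hypoxia in orange, filled where the limma adjusted p was under 0.05. Under normoxia 20 of 27 members fell, to −3.30 for DDIT4, and under hypoxia 11 rose, to 1.60 for CA9, and 7 fell.

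Sterol and lipid genes fell as well. Of 25 genes of cholesterol synthesis and uptake, which SREBP2 drives, 18 fell and none rose (19 and 2 adjusted over the list alone, median −0.46). INSIG1 (−1.64), which retains the sterol sensor in the endoplasmic reticulum, and the synthesis enzyme HMGCS1 (−1.04) were among those that fell. Of 19 genes of fatty acid synthesis and storage, 9 fell and 1, DGAT2 (0.54), rose (9 and 2 adjusted over the list alone, median −0.18), with SCD (−1.18), HILPDA (−0.99), SREBF1 (−0.76) and FASN (−0.62) lowest. Of 21 targets of the antioxidant regulator NRF2, 10 fell and 2 rose (12 and 2 adjusted over the list alone, median −0.22). The cystine transporter SLC7A11 (−0.85) and NQO1 (−0.81) fell, while the efflux pump ABCC3 (1.10) and HMOX1 (0.35) rose. Of 17 genes of ferroptosis and iron handling, 8 fell and 3 rose (8 and 4 adjusted over the list alone, median −0.12), including SLC7A11, CHAC1 (−0.76), the ferritin light chain gene FTL (−0.63) and the transferrin receptor gene TFRC (−0.47), against PTGS2 (0.45), HMOX1 and NCOA4 (0.22). Camera gave an adjusted p of 2.74e-11, 0.000313, 1.03e-05 and 0.0196 for these 4 lists in this order, and none held, at adjusted p = 0.263 to 0.282 with an estimated correlation. Among the risers, limma adjusted p passed 0.05 without control replicate 1 for NCOA4 (0.144), without control replicate 2 for HMOX1 (0.145) and NCOA4 (0.0707) and without knockdown replicate 1 for HMOX1 (0.124).

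Gene lists of translation and of mitochondrial proteins had small negative medians, and in several of them most members were not called. Of 57 cytosolic ribosomal protein genes, 33 fell and none rose (40 and 1 adjusted over the list alone, median −0.23), RPL28 (−0.66), RPS9 (−0.66), RPL3 (−0.63) and RPL13A (−0.56) most. Of 38 mitochondrial ribosome genes, 18 fell and 1, MRPS14 (0.22), rose (18 and 1 adjusted over the list alone, median −0.18), MRPL37 (−0.71) and MRPL45 (−0.66) most. Nuclear genes of respiratory complexes II to V had 11 of 39 lower and 2 higher (11 and 2 adjusted over the list alone, median −0.15), with ATP synthase subunits ATP5MC1 (−0.72) and ATP5F1D (−0.60) lowest and ATP5F1C (0.22) and UQCR11 (0.28) higher. Complex I had 8 of 36 lower and 3 higher (7 and 3 adjusted over the list alone, median −0.09), with NDUFV2 (−0.73) and NDUFB10 (−0.39) lowest and NDUFA5 (0.32), NDUFB2 (0.26) and NDUFB9 (0.21) higher. Chaperones and proteases of the mitochondrial unfolded protein response had 8 of 14 lower and none higher (10 and 1 adjusted over the list alone, median −0.19), led by CLPP (−0.70) and LONP1 (−0.60). Of 20 genes of the TCA cycle and pyruvate dehydrogenase, 7 fell and 1, SUCLA2 (0.35), rose (9 and 1 adjusted over the list alone, median −0.15), SUCLG2 (−0.57) and IDH3B (−0.44) most. Mitochondrial DNA maintenance had 6 of 19 lower and 1, RRM2B (0.31), higher (7 and 1 adjusted over the list alone, median −0.14). By camera, adjusted p was 8.36e-15, 1.21e-07, 4.35e-06, 0.00745, 9.93e-05, 0.000685 and 0.000898 for these 7 lists in this order, and none held, at adjusted p = 0.263 to 0.406 with an estimated correlation. The complex I call was lost without knockdown replicate 2 (median −0.043, adjusted p = 0.0753). Single libraries also decided several small rises, whose limma adjusted p was over 0.05 without control replicate 1 for ATP5F1C (0.2), MRPS14 (0.172), NDUFA5 (0.0554), NDUFB9 (0.189) and UQCR11 (0.155), without control replicate 2 for ATP5F1C (0.0578), MRPS14 (0.157), NDUFA5 (0.0768), NDUFB2 (0.202), NDUFB9 (0.0908), RRM2B (0.0669) and UQCR11 (0.0562), without knockdown replicate 1 for MRPS14 (0.0529), NDUFB2 (0.119), NDUFB9 (0.051) and UQCR11 (0.0701) and without knockdown replicate 2 for ATP5F1C (0.0575) and NDUFA5 (0.0552). Among the mitochondrial genome's own mRNAs, MT-ND1 (0.42) and MT-ND5 (0.29) passed the test, at limma adjusted p of 0.0393 and 0.0388 over all genes and neither adjusted over the list alone. MT-ND1 did not pass without control replicate 2 (0.29, adjusted p = 0.0954) or knockdown replicate 1 (0.28, 0.154), nor MT-ND5 without control replicate 1 (0.18, 0.205), knockdown replicate 1 (0.28, 0.119) or knockdown replicate 2 (0.31, 0.105).

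Growth and replication genes made up the remaining lower lists. MYC targets and ribosome biogenesis genes had 7 of 28 lower and 1, CAD (0.29), higher (7 and 1 adjusted over the list alone, median −0.11), among them MYC (−0.67) and LDHA (−0.59). DNA replication genes had 12 of 37 lower and 3 higher (13 and 3 adjusted over the list alone, median −0.09), with MCM6 (−0.51) lowest and the cyclins CCNE1 (0.49) and CCNE2 (0.40) and RPA2 (0.17) higher. Replication-dependent histones had 5 of 9 lower and none higher (5 and 0 adjusted over the list alone, median −0.29), H1-2 (−0.52) among them. Nucleotide synthesis had 7 of 26 lower and 5 higher (10 and 5 adjusted over the list alone, median −0.09), with PRPS1 (−0.40) lowest and SAMHD1 (0.59), which degrades nucleotides, ADSS2 (0.32), CAD, DUT (0.19) and ATIC (0.17) higher. The camera adjusted p was 0.000346, 0.000387, 0.00311 and 0.0148 for these 4 lists in this order, and none held, at adjusted p = 0.268 to 0.379 with an estimated correlation. The nucleotide synthesis call was lost without control replicate 2 (median −0.041, adjusted p = 0.0932). Small rises had a limma adjusted p over 0.05 without control replicate 1 for ATIC (0.256), CAD (0.0617), CCNE2 (0.054), DUT (0.147) and RPA2 (0.212), without control replicate 2 for ATIC (0.163), DUT (0.179) and RPA2 (0.244) and without knockdown replicate 2 for ATIC (0.072), CCNE2 (0.0529), DUT (0.0598) and RPA2 (0.0959).

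The lists that rose under normoxia belonged to immune recognition, cell contact signalling and cytokines. Of 19 genes of antigen processing and MHC class I, 15 rose and 1 fell (15 and 1 adjusted over the list alone, median 0.49), among them PSMB9, HLA-B, the peptide-trimming enzyme ERAP1 (0.88) and PSMB8 (0.83). The gene that fell, the chaperone CALR (−0.18, adjusted p = 0.036), did not pass without control replicate 1 (−0.17, 0.213), control replicate 2 (−0.18, 0.172) or knockdown replicate 2 (−0.16, 0.0723). Of 27 interferon-stimulated genes, 15 rose and 1, OAS3 (−0.32), fell (16 and 1 adjusted over the list alone, median 0.41), with IFIT3 (0.93), UBE2L6 (0.91), IFI35 (0.78) and IFI6 (0.78) highest. Of 19 targets of YAP and TEAD, effectors of Hippo signalling, 10 rose and none fell (12 and 0 adjusted over the list alone, median 0.27), including F3 (0.75), CRIM1 (0.75), FJX1 (0.67) and MYOF (0.52). The widely used targets CCN1 (−0.035) and CCN2 (−0.0022) did not pass, and both values turned positive when mitochondrial genome genes were left out, CCN2 also without control replicate 2 (0.080) or knockdown replicate 2 (0.14). Of 25 NF-kB targets and inflammatory cytokines, 13 rose and 4 fell (14 and 5 adjusted over the list alone, median 0.27). LTB, IL32 (1.09) and the adhesion molecule ICAM1 (0.88) rose, and IER3, CXCL3 (−0.50), CXCL8 (−0.49) and LIF (−0.44) fell. Camera gave an adjusted p of 7.58e-07, 0.000403, 0.0102 and 0.0449 for these 4 lists in this order, and none held, at adjusted p = 0.263 to 0.526 with an estimated correlation. The NF-kB call was lost without knockdown replicate 1 (median 0.32, adjusted p = 0.0506) or knockdown replicate 2 (median 0.30, adjusted p = 0.075).

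In the limma fit of the normoxia libraries, 4818 of 14090 tested genes passed an adjusted p of 0.05, 3165 higher and 1653 lower, with 6546 at an unadjusted p under 0.05. Of these, 188 changed at least 2-fold, 126 higher and 62 lower. The groups did not overlap in 70.5% of tested genes, against 33.3% by chance. Without control replicate 1 the count was 3027 and without control replicate 2 it was 3166. Median-of-ratios scaling gave 2369 higher and 2323 lower genes, quantile normalization 2242 and 2048, and leaving out mitochondrial genome genes 3976 and 1290, so the size of the surplus of higher genes depended on the scaling. A correction for GC content and transcript length moved the median of interferon-stimulated genes from 0.41 to 0.28 and of NF-kB targets from 0.27 to 0.20. It moved the median of YAP and TEAD targets from 0.27 to 0.18 and of DNA replication from −0.093 to −0.19. The median of mitochondrial DNA maintenance went from −0.14 to −0.23 and that of nucleotide synthesis from −0.090 to −0.14.

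The comparison under hypoxia asks what differs with the PPA2 hairpin in cells short of oxygen. Knockdown cells had higher TXNIP and HMOX1 and unequal changes among the transcripts of the mitochondrial genome. Transcripts of heat shock chaperones, ribosomes and respiratory complexes were lower, though none of these gene lists held with an estimated correlation and 2 residual degrees of freedom. Small nucleolar RNA genes fell between the same libraries, 63 of 67 tested, with a median of −1.71. TXNIP rose from 1.67 to 40.8 FPKM (log2 fold change 3.97 ± 0.08 SE, 15.7-fold, limma adjusted p = 1.44e-06). HMOX1, the haem-degrading enzyme of the antioxidant response, rose from 5.27 to 55.2 FPKM (3.17 ± 0.08, 8.97-fold, limma adjusted p = 4.6e-06). The heat shock genes HSPA1B and DNAJB1 fell from 292 to 29.9 FPKM (−3.24 ± 0.08, 9.47-fold, limma adjusted p = 3.94e-06) and from 443 to 57.6 FPKM (−2.92 ± 0.06, 7.57-fold, limma adjusted p = 1.81e-06).

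The 10 largest rises were led by the mitochondrial genome. MT-ND1, a complex I subunit, rose from 87.1 and 76.8 FPKM in the control libraries to 1443 and 1415 FPKM in the knockdown libraries (4.11 ± 0.08). MT-TY and MT-TC, mitochondrial tRNA genes, were listed at 0 in both control libraries and at 354 and 391 FPKM (MT-TY) and 139 and 151 FPKM (MT-TC) in the knockdown libraries. The mitochondrial tRNA genes MT-TL1 (6.08 ± 0.42), MT-TE (4.80 ± 0.16), MT-TD (4.5 ± 0.11), MT-TF (4.41 ± 0.14), MT-TP (4.14 ± 0.17) and MT-TV (3.59 ± 0.28) rose as well, and TXNIP completed the 10. Of the 10 largest falls, 4 were small nucleolar RNA genes, which guide ribosomal RNA modification and carry no poly(A) tail: SNORD14E (−5.84 ± 0.27), SNORD6 (−3.59 ± 0.25), SNORA72 (−3.40 ± 0.15) and SNORD38A (−3.36 ± 0.15). The others were HSPA6, a strictly inducible heat shock gene that went from 17.0 to 0.274 FPKM (−3.82 ± 0.11), HSPA1A (−3.37 ± 0.09), HSPA1B, the mitochondrial import gene TOMM6 (−3.19 ± 0.48) and the transcripts AC104695.3 (−3.61 ± 0.19) and AC004080.3 (−3.17 ± 0.17). Values of such short genes, of overlapping transcripts and of read-through transcripts depend on how reads were assigned. Among protein-coding genes, a ranking chosen after the values were seen, the 10 largest rises were those of MT-ND1, TXNIP, MT-ND6 (3.52 ± 0.11), HMOX1, MT-CO1 (2.82 ± 0.10), MT-ND5 (2.70 ± 0.08), the inositol transporter SLC5A3 (2.20 ± 0.12), NPNT (2.07 ± 0.11), SPTSSB (2.0 ± 0.08) and the adhesion molecule NECTIN1 (1.95 ± 0.11). Other falls included AC023055.1 (−2.66 ± 0.12), ANKRD37, which went from 157 to 28.2 FPKM (−2.43 ± 0.08), and the read-through transcript TMEM189-UBE2V1, listed at 0 in both knockdown libraries. Limma adjusted p-values of the genes of this paragraph with a stated fold change lay between 1.44e-06 (MT-ND1) and 0.0014 (TOMM6).

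The 13 mRNAs of the mitochondrial genome, which code for core subunits of the respiratory chain and are made from long shared precursors, went in both directions. MT-ND1, MT-ND6, MT-CO1, MT-ND5, MT-ND4 (1.93) and MT-ND4L (1.86) rose, and MT-ND3 (−1.24), MT-ND2 (−1.08), MT-CYB (−0.90) and MT-CO2 (−0.63) fell (the same 6 and 4 adjusted over the list alone). MT-CO1 stood at 1128 and 986 FPKM in the control libraries and at 7489 and 7431 FPKM in the knockdown libraries. MT-ATP6 (−0.21, adjusted p = 0.163), MT-CO3 (−0.065, 0.645, positive under median-of-ratios scaling and, at 0.074, without control replicate 1) and MT-ATP8 (−0.24, 0.0829) did not pass. Single libraries decided 4 of these genes: MT-CO2 did not pass without knockdown replicate 1 (−0.66, 0.0893) or 2 (−0.60, 0.116), while MT-ATP6 (−0.36, 0.00135) and MT-CO3 (−0.20, 0.00404) passed without control replicate 2 and MT-ATP8 passed without control replicate 1 (−0.14, 0.014) or 2 (−0.35, 0.00141). The median of the list was −0.065 and its mean 0.97, which differ in sign, and the median turned positive under median-of-ratios scaling, without control replicate 1 (0.074) and after a correction for GC content and transcript length (0.22). The list test gave a camera adjusted p of 0.137 (direction up, but down under quantile normalization) and an adjusted p = 0.702 with an estimated correlation. By camera, adjusted p was 0.0106 without knockdown replicate 1 and 0.0116 without knockdown replicate 2. The ribosomal RNA genes MT-RNR2 (1.85) and MT-RNR1 (1.55) rose, as they did under normoxia (0.79 and 0.54). Transcripts of the 13 genes made up 8.07% and 7.20% of all FPKM in the control libraries and 10.7% and 10.5% in the knockdown libraries. Small nucleolar RNA genes moved with the same groups: of 67 tested, 63 fell and none rose, with a median of −1.71.

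**Figure D3:**
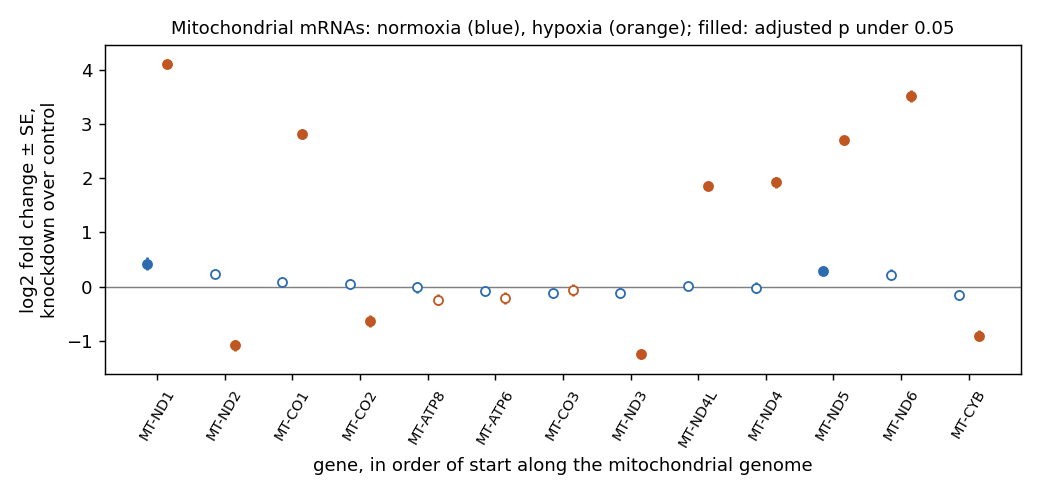
Log2 fold change (knockdown over control, log2 of value + 1, points) with its SE (bars, n = 2 libraries per group) of the 13 mRNAs of the mitochondrial genome in order of their position, under normoxia in blue and hypoxia in orange, filled where the limma adjusted p was under 0.05. Under hypoxia the values run from −1.24 for MT-ND3 to 4.11 for MT-ND1, and MT-CO3 is positive under median-of-ratios scaling.

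Genes of protein synthesis fell together under hypoxia. Of 30 MYC targets and ribosome biogenesis genes, 28 fell and 1, LDHA (0.78), rose (28 and 1 adjusted over the list alone, median −0.87), with the import factor IPO4 (−1.75), the ribosomal RNA methyltransferase NOP2 (−1.49), TFRC (−1.39) and SRM (−1.33) lowest. Of 57 cytosolic ribosomal protein genes, 46 fell and none rose (50 and 0 adjusted over the list alone, median −0.46), including RPS23 (−1.20) and RPL38 (−1.05). Of 38 mitochondrial ribosome genes, 35 fell and none rose (36 and 0 adjusted over the list alone, median −0.59), MRPL4 (−1.38), MRPL20 (−1.13) and MRPL12 (−1.13) most. Of 18 heat shock genes, 16 fell and none rose (16 and 0 adjusted over the list alone, median −0.62), among them the mitochondrial chaperonin HSPE1 (−1.44). The same libraries differed in small nucleolar RNA genes, with 63 of 67 lower and a median of −1.71. The camera adjusted p was 1.66e-08, 3.16e-08, 1.66e-08 and 1.62e-06 for these 4 lists in this order, and none held, at adjusted p = 0.289 to 0.513 with an estimated correlation.

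Nuclear genes of mitochondrial energy metabolism fell too. Respiratory complexes II to V had 34 of 39 genes lower and none higher (35 and 0 adjusted over the list alone, median −0.59), with ATP5ME (−1.37), UQCRQ (−1.19) and UQCRB (−1.18) lowest. Complex I had 27 of 37 lower and 1, NDUFC2 (0.57), higher (29 and 1 adjusted over the list alone, median −0.47), NDUFB1 (−1.07) and NDUFS5 (−0.99) lowest. The mitochondrial unfolded protein response had 12 of 14 lower and none higher (12 and 0 adjusted over the list alone, median −0.64), HSPE1 and TRAP1 (−1.06) lowest. Mitochondrial DNA maintenance had 16 of 19 lower and 1, RRM2B (0.26), higher (16 and 1 adjusted over the list alone, median −0.53), with SSBP1 (−1.0) and the polymerase subunit POLG2 (−0.90) among the lower. The TCA cycle and pyruvate dehydrogenase had 13 of 20 lower and 1, IDH2 (0.41), higher (13 and 1 adjusted over the list alone, median −0.37), IDH3B (−1.02) and citrate synthase CS (−0.69) among them. Camera gave an adjusted p of 1.41e-07, 1.32e-05, 0.000431, 0.000483 and 0.0137 for these 5 lists in this order, and none held, at adjusted p = 0.289 to 0.506 with an estimated correlation. The rise of RRM2B rested on every library, at a limma adjusted p of 0.107 without control replicate 1, 0.0528 without control replicate 2, 0.0809 without knockdown replicate 1 and 0.322 without knockdown replicate 2. A correction for GC content and transcript length moved medians from −0.59 to −0.36 (complexes II to V), from −0.47 to −0.31 (complex I), from −0.46 to −0.31 (cytosolic ribosomal proteins), from −0.37 to −0.23 (TCA cycle and pyruvate dehydrogenase) and, by less, from −0.59 to −0.49 (mitochondrial ribosome).

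Proliferation and stress-signalling genes were also lower. Of 30 genes of G2 and mitosis, 22 fell and none rose (23 and 0 adjusted over the list alone, median −0.42), with cyclin CCNB1 (−1.07) and the kinase AURKA (−1.05) lowest. Of 37 DNA replication genes, 27 fell and 2, FEN1 (0.33) among them, rose (27 and 2 adjusted over the list alone, median −0.49), ORC6 (−1.04) and RFC3 (−1.02) lowest. Of 26 nucleotide synthesis genes, 15 fell and 1, SAMHD1 (0.47), rose (15 and 1 adjusted over the list alone, median −0.58), with CTPS1 (−1.45) and NME1 (−1.35) lowest. Of 26 ATF4 targets, 17 fell and 3 rose (17 and 3 adjusted over the list alone, median −0.33). PPP1R15A (−1.78), DDIT4 (−1.45), DDIT3 (−1.40) and SLC3A2 (−1.19) fell, and SESN2 (0.83), VLDLR (0.66) and TRIB3 (0.51) rose. Of 24 immediate early genes, 13 fell and 4 rose (14 and 4 adjusted over the list alone, median −0.26). JUN (−2.28), EGR1 (−1.93) and IER3 (−1.90) fell, and BTG2 (1.35), DUSP4 (0.76), KLF2 (0.68) and KLF4 (0.32) rose. By camera, adjusted p was 0.000197, 8.05e-05, 0.00229, 0.00953 and 0.0342 for these 5 lists in this order, and none held, at adjusted p = 0.289 with an estimated correlation. Limma adjusted p passed 0.05 without knockdown replicate 1 for KLF4 (0.0551) and SAMHD1 (0.0617) and without knockdown replicate 2 for FEN1 (0.0602).

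Lists that rose under hypoxia covered glycolysis, antigen presentation, metal binding and cell contacts. Of 20 glycolysis genes, 13 rose and 3, LDHB (−0.46), SLC2A1 (−0.37) and PFKM (−0.28), fell (14 and 3 adjusted over the list alone, median 0.34), with ALDOC (1.35), the lactate exporter SLC16A3 (0.90) and LDHA highest. Of 19 genes of antigen processing and MHC class I, 13 rose and 2, CD274 (−0.52) and PSME2 (−0.29), fell (13 and 2 adjusted over the list alone, median 0.34), with HLA-B (1.57), ERAP1 (1.43) and PSMB9 (1.01) highest. Of 28 interferon-stimulated genes, 13 rose and 3, IRF9 (−0.70), IRF7 (−0.42) and STAT2 (−0.32), all transcription factors of interferon signalling, fell (12 and 3 adjusted over the list alone, median 0.23), with MX2 (1.0), ISG20 (0.95) and IFI6 (0.91) highest. All 6 tested genes of the metallothionein and zinc list rose (6 adjusted over the list alone, median 0.88), including MT1X (1.06), MT1E (0.97) and the zinc exporter SLC30A1 (0.95), although the MT1 genes are similar enough to share reads. Of 27 epithelial junction and keratin genes, 15 rose and 4 fell (15 and 4 adjusted over the list alone, median 0.39). CLDN1 (1.06), DSC2 (1.06) and E-cadherin, CDH1 (0.90), rose, and OVOL2 (−0.85), ELF3 (−0.80), ESRP1 (−0.59) and CLDN7 (−0.53) fell. Of 16 genes of epithelial-mesenchymal transition and matrix, 10 rose and 1, CCN1 (−0.64), fell (10 and 1 adjusted over the list alone, median 0.44), with the protease PLAU (1.23) among the higher. The camera adjusted p was 0.00173, 0.00173, 0.0192, 0.00173, 0.00333 and 0.00333 for these 6 lists in this order, and none held, at adjusted p = 0.289 to 0.382 with an estimated correlation. Several falls within these lists had a limma adjusted p over 0.05 without control replicate 2 for CD274 (0.0506) and STAT2 (0.171), without knockdown replicate 1 for CD274 (0.0933), PFKM (0.0715), PSME2 (0.118) and SLC2A1 (0.072) and without knockdown replicate 2 for PFKM (0.0706), SLC2A1 (0.0764) and STAT2 (0.22).

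A further 4 lists passed narrowly. Autophagy and mitophagy genes had 8 of 27 higher and 2 lower (8 and 2 adjusted over the list alone, median 0.10), with the mitophagy receptor BNIP3L (1.53) and the kinase PINK1 (0.74) highest and ATG16L1 (−0.33) and BECN1 (−0.22) lower. The endoplasmic reticulum unfolded protein response had 12 of 24 higher and 5 lower (12 and 5 adjusted over the list alone, median 0.23), SEL1L (0.67) highest and DNAJB11 (−0.61), SYVN1 (−0.57), SEC61B (−0.44), MANF (−0.38) and SDF2L1 (−0.27) lower. WNT targets and intestinal stem cell genes had 12 of 20 higher and 4 lower (12 and 4 adjusted over the list alone, median 0.33). The stem cell marker PROM1 (0.90) rose, while LGR5 (−1.65), which marks intestinal stem cells, and RNF43 (−1.04), a negative regulator of WNT receptors, fell with SOX9 (−0.33) and ASCL2 (−0.29). Cholesterol genes had 11 of 25 higher and 4 lower (12 and 4 adjusted over the list alone, median 0.16), with HSD17B7 (−0.59), IDI1 (−0.32) and MVD (−0.31) among the lower. Camera gave an adjusted p of 0.0424, 0.043, 0.0462 and 0.0462, and none held, at adjusted p = 0.289 to 0.414 with an estimated correlation. Without control replicate 2 the p was 0.0999 for autophagy, 0.0862 for WNT targets and 0.0592 for cholesterol genes. Without knockdown replicate 1 it was 0.0736 for the endoplasmic reticulum list, 0.0736 for WNT targets and 0.0542 for cholesterol genes. Without knockdown replicate 2 it was 0.0866, 0.0559 and 0.0559 for the same 3 lists. Of the falls, some had a limma adjusted p over 0.05 without control replicate 1 for SDF2L1 (0.0797), without control replicate 2 for SDF2L1 (0.0755), without knockdown replicate 1 for ASCL2 (0.0731), ATG16L1 (0.0592), BECN1 (0.141), IDI1 (0.0843) and MVD (0.0669) and without knockdown replicate 2 for ASCL2 (0.0949), ATG16L1 (0.0724), BECN1 (0.177), MVD (0.0535), SDF2L1 (0.272) and SOX9 (0.0612).

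HIF targets did not move one way under hypoxia. Of 27 tested, 11 rose and 7 fell (11 and 7 adjusted over the list alone, median 0.04, camera adjusted p = 0.154, and adjusted p = 0.382 with an estimated correlation). CA9, the acid-extruding carbonic anhydrase, rose from 0.418 to 3.31 FPKM (1.60), and BNIP3L and EGLN3 (1.08) rose. ANKRD37 and ADM (−1.62) fell, ADM from 194 to 62.4 FPKM.

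In the limma fit of the hypoxia libraries, 7637 of 13080 tested genes passed an adjusted p of 0.05, 3219 higher and 4418 lower, with 8290 at an unadjusted p under 0.05. Of these, 1037 changed at least 2-fold, 355 higher and 682 lower. The groups did not overlap in 80.4% of tested genes, against 33.3% by chance. Median-of-ratios scaling gave 3834 higher and 3875 lower genes and quantile normalization 3894 and 3757, so the surplus of lower genes depended on the scaling. With the mitochondrial genome genes left out and values rescaled to a common total, a choice made after results were seen, the median log2 fold change of all genes moved up by 0.167 and the split became 4578 higher and 2998 lower. A correction for GC content and transcript length moved the median of HIF targets from 0.04 to 0.14, of cholesterol genes from 0.16 to 0.29, of MHC class I genes from 0.34 to 0.55 and of autophagy genes from 0.10 to 0.15.

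**Figure D4:**
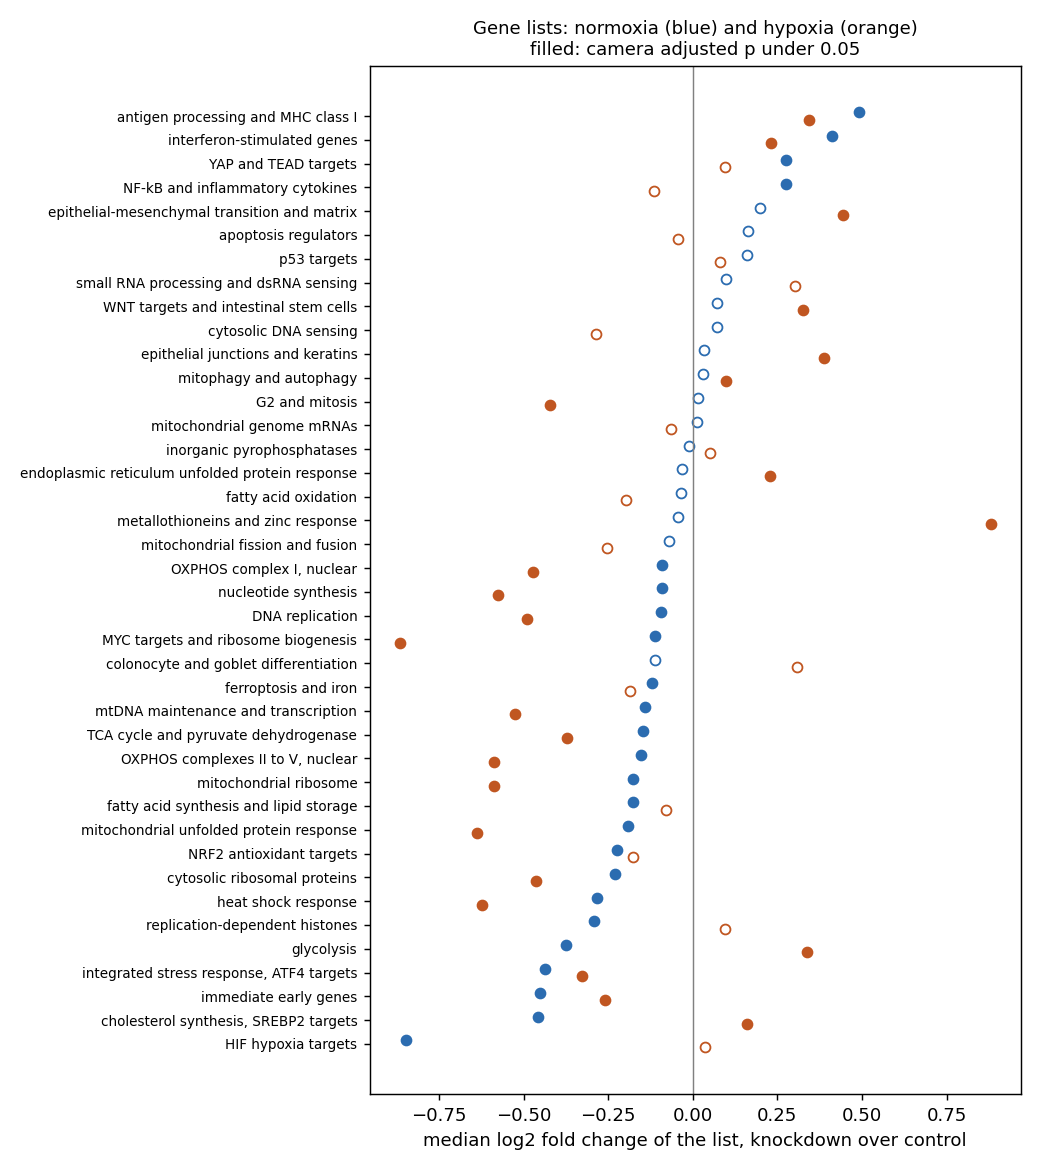
Median log2 fold change (knockdown over control, log2 of value + 1) of each gene list tested under normoxia (blue) and hypoxia (orange), filled where the camera adjusted p at the preset correlation was under 0.05. HIF targets lie at −0.85 under normoxia and 0.04 under hypoxia, MHC class I genes at 0.49 and 0.34, and the median of mitochondrial genome mRNAs under hypoxia is positive under median-of-ratios scaling and after a correction for GC content and length.

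Responses to PPA2 knockdown at the 2 oxygen levels were compared over the 12060 genes tested in both fits. TXNIP, HLA-B, ERAP1 and NPNT rose and DDIT4, ANKRD37, ADM, JUN and HSPA1B fell at both. The log2 fold changes correlated across genes with Pearson r = 0.46 and Spearman rho = 0.46, a description, since genes are not independent replicates. Higher calls overlapped in 1465 genes against 712 expected for independent lists (odds ratio 5.24, two-sided Fisher's exact p = 2.53e-278), and lower calls in 952 genes against 519 expected (odds ratio 3.90, p = 8.58e-131). Fisher's test also treats genes as independent, so its p-values overstate the evidence and do not measure replication between libraries. Of 2878 genes called at both levels, 84.0% had the same sign, 323 were higher under normoxia and lower under hypoxia, and 138 the reverse. No libraries are shared between the comparisons.

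**Figure D5:**
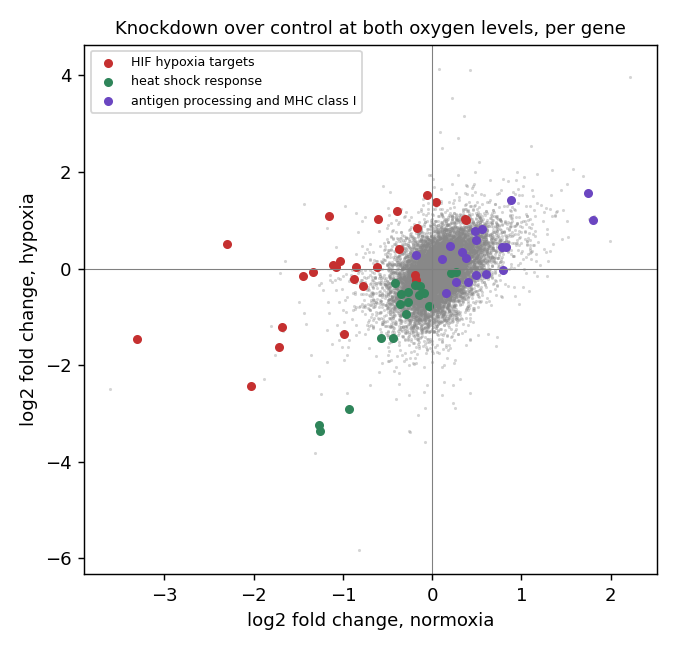
Log2 fold change of each gene tested at both oxygen levels (points), normoxia on the horizontal and hypoxia on the vertical axis, with HIF targets in red, heat shock genes in green and MHC class I genes in purple. Pearson r across genes is 0.46.

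The difference between both responses was tested as an interaction, with positive values where the log2 fold change was higher under hypoxia. NDRG1 fell under normoxia and rose under hypoxia (from 211 to 301 FPKM, 0.51), a difference of 2.81 ± 0.14 (limma adjusted p = 1.97e-06). ALDOC (2.78 ± 0.14) and EGLN3 (2.24 ± 0.09) differed in the same way, and HMOX1 rose more under hypoxia (2.81 ± 0.14, limma adjusted p = 2.09e-06). HSPA6 (−2.51 ± 0.15) and HSPA1A (−2.12 ± 0.15) were lower by a larger amount under hypoxia. The 5 largest positive differences were those of the mitochondrial tRNA genes MT-TY, MT-TC, MT-TL1, MT-TE and MT-TD, all listed at 0 in the 4 normoxia libraries, and the 5 largest negative ones those of SNORD14E (−5.02 ± 0.35), SNORD6 (−3.51 ± 0.31), TOMM6 (−3.23 ± 0.58), AC004080.3 and SNORA33 (−3.15 ± 0.21). AC004080.3 was also listed at 0 in the 4 normoxia libraries and TOMM6 at no more than 0.108 RPKM, so their differences, like those of the tRNA genes, restate the change under hypoxia. Among the mitochondrial mRNAs, MT-ND1 (3.69 ± 0.16) and MT-ND6 (3.30 ± 0.17) differed most.

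The HIF list had the strongest difference by its test, with a median of −0.85 under normoxia and 0.04 under hypoxia. The hypoxia libraries, in which 63 of 67 small nucleolar RNA genes were lower with knockdown, enter every difference. Of 27 genes, 22 responded higher under hypoxia and 1, HILPDA (−0.38), lower (22 and 1 adjusted over the list alone, median 1.01), with NDRG1, EGLN3, DDIT4 (1.85) and CA9 (1.82) highest. Glycolysis had 17 of 20 higher and 2, LDHB (−0.43) and PFKM (−0.30), lower (17 and 2 adjusted over the list alone, median 0.71), led by ALDOC, PGK1 (1.61) and SLC16A3 (1.40). Cholesterol genes had 17 of 25 higher and none lower (18 and 0 adjusted over the list alone, median 0.71), with INSIG1 (1.81) among them. Metallothioneins had 5 of 6 higher (5 adjusted over the list alone, median 0.85), MT1X (1.37) most. MYC targets had 27 of 30 lower and 2, LDHA (1.37) and MYC (0.51), higher (27 and 2 adjusted over the list alone, median −0.80). Lower responses under hypoxia also ran through G2 and mitosis (21 of 30 lower, 22 adjusted over the list alone, median −0.45), heat shock genes (13 of 18, 14 adjusted over the list alone, median −0.41) and complex I (24 of 37, 24 adjusted over the list alone, median −0.45), with none higher in these 3. Of the MYC, G2 and complex I lists, 28, 29 and 36 genes reached the minimum mean under normoxia. Differences of their other members mainly restate the change under hypoxia. NF-kB targets had 16 of 25 lower and 1, CX3CL1 (0.75), higher (17 and 1 adjusted over the list alone, median −0.57), with the chemokines CXCL2 (−1.84), CCL20 (−1.63), CXCL1 (−1.43) and CXCL8 (−1.42) lowest. By camera, adjusted p was 2.89e-15, 2.9e-12, 7.47e-12, 0.000163, 5.99e-08, 2.95e-05, 6.47e-05, 0.00088 and 0.00132 for these 9 lists in this order, and none held, at adjusted p = 0.115 to 0.307 with an estimated correlation. Without control normoxia replicate 2 the limma adjusted p of PFKM was 0.0691. MHC class I and interferon-stimulated genes passed as higher lists at both oxygen levels, at the preset correlation only. For a difference they gave camera adjusted p of 0.711 and 0.925 (adjusted p = 0.859 and adjusted p = 0.921 with an estimated correlation). Camera sets a list against the other genes, so members can still differ. Of 19 MHC class I genes, 5 responded higher and 9 lower under hypoxia (median −0.18). Of 27 interferon-stimulated genes, 4 responded higher and 6 lower (median −0.21). The fry list test gave adjusted p of 0.0279 and 0.00412, both in the lower direction.

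In the limma fit of all 8 libraries, 5760 of 13585 genes passed an adjusted p of 0.05 for a difference, 1815 higher and 3945 lower, with 6935 at an unadjusted p under 0.05 and 773 at a difference of at least 2-fold. Other scalings moved the median of all genes up by 0.119 (median-of-ratios), 0.133 (quantile normalization) and 0.115 (without mitochondrial genome genes) and gave 2763 higher and 2869 lower, 2891 and 2763, and 2552 and 2800 genes.

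Hypoxia and normoxia levels of the same cells were set side by side to check the oxygen labels, without a test, since oxygen level and table cannot be told apart. In control cells, HIF targets lay above the rest: their median log2 ratio of hypoxia over normoxia was 0.67, against −0.26 for all genes, with 24 of 27 members above the latter, at percentile 100 among 10000 random lists matched on expression. In knockdown cells the median was 1.85 against −0.37, with 27 of 27 above. On the value + 1 scale, ANKRD37 was 10.3 times as high under hypoxia in control cells and 7.71 times in knockdown cells, ADM 4.61 and 4.92 times, PFKFB4 2.75 and 6.57 times, NDRG1 2.43 and 17.0 times, EGLN3 1.44 and 6.81 times, SLC2A1 1.30 and 1.73 times, VEGFA 1.20 and 2.91 times, CA9 1.02 and 3.62 times and PDK1 0.893 and 1.41 times. MYC targets (median −0.91, percentile 0), genes of G2 and mitosis (−0.76, percentile 0.13) and NF-kB targets (−0.78, percentile 0.03) lay low in control cells under hypoxia, and cholesterol genes high (0.24, percentile 99.98).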

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

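Each value here is a difference of knockdown responses between hypoxia and normoxia that passed its test: 10 genes by the limma interaction and 25 gene lists by camera on the same term. None of the lists passed with an estimated correlation, a test with 4 residual degrees of freedom. The test of library preparation by small nucleolar RNA genes was written after the results were seen, the others before they were run.

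Among genes, the log2 differences were 8.54 for MT-TY, 7.19 for MT-TC, 6.08 for MT-TL1, 4.80 for MT-TE and 4.5 for MT-TD. All 5 genes were listed at 0 in the 4 normoxia libraries, so these values restate the change under hypoxia and test no difference of responses. They depend on the pseudocount and set no bound for MT-TY and MT-TC, which were listed at 0 in both control hypoxia libraries too. The largest negative differences were −5.02 for SNORD14E, −3.51 for SNORD6, −3.23 for TOMM6, −3.17 for AC004080.3 and −3.15 for SNORA33. AC004080.3 was listed at 0 and TOMM6 at no more than 0.108 RPKM in the normoxia libraries, so their values restate the change under hypoxia as well.

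Among lists, the median differences were 1.01 for HIF targets, 0.71 for glycolysis, 0.71 for cholesterol synthesis, 0.85 for metallothioneins, 0.47 for colonocyte and goblet genes, 0.42 for replication-dependent histones, 0.25 for WNT targets, 0.20 for epithelial junctions, 0.20 for the endoplasmic reticulum unfolded protein response, 0.12 for fatty acid synthesis, 0.090 for ATF4 targets, 0.077 for NRF2 targets and 0.060 for mitochondrial genome mRNAs. Negative medians were −0.80 for MYC targets, −0.57 for NF-kB targets, −0.51 for complexes II to V, −0.45 for complex I, −0.45 for G2 and mitosis, −0.44 for the mitochondrial ribosome, −0.41 for heat shock genes, −0.38 for the mitochondrial unfolded protein response, −0.38 for nucleotide synthesis, −0.34 for mitochondrial DNA maintenance, −0.32 for DNA replication and −0.21 for cytosolic ribosomal proteins. The mitochondrial mRNA list was lost without control hypoxia replicate 2 (−0.079, adjusted p = 0.0745), and its median was −0.46 after quantile normalization. Cytosolic ribosomal proteins were lost without knockdown normoxia replicate 1 (−0.18, 0.164), control hypoxia replicate 1 (−0.14, 0.272) or knockdown hypoxia replicate 1 (−0.21, 0.0745). Fatty acid synthesis was lost without knockdown normoxia replicate 2 (0.065, 0.119) or knockdown hypoxia replicate 1 (0.11, 0.0745).

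The unequal change of the 13 mitochondrial mRNAs under hypoxia, 6 higher and 4 lower, could come from bias, shared reads, library preparation or a real change in how the mitochondrial genome is expressed. A correction for GC content and length left a gap of 5.26 between the highest and lowest log2 fold change, against 5.35 before. The correction was fitted on all genes and removed 3.78% of the variance of their log2 fold changes. Median transcript length was 784 for these mRNAs and 3403 for all genes. The correction therefore speaks only against a GC and length trend shared by all genes. A bias particular to short or mitochondrial transcripts stays open. For MT-ND1, MT-CO1, MT-ND4 and MT-ND5, which rose, 153 nuclear copies summed to 4.59 FPKM in control and 25.5 FPKM in knockdown libraries. This was a gain in control of −0.163% of the missing 12833 FPKM, so those copies did not hold the missing signal of these 4 genes. Shared reads that were dropped in counting would not show in this sum, so an effect of shared reads stays open. The other mitochondrial mRNAs were not tested. Small nucleolar RNA genes had a median of −1.64 relative to that of all genes under hypoxia and −0.088 under normoxia, which would follow from a difference in RNA or library preparation between control and knockdown libraries, and that explanation stays open. How reads of neighbouring mitochondrial genes were assigned was not tested, so no biological cause is claimed.

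The fall of heat shock genes under hypoxia held after a correction for GC content and length (median −0.52) and without the mitochondrial genome genes (median −0.43). A GC and length trend shared by all genes, or the signal taken by mitochondrial genome genes, is therefore excluded as the only cause. The same libraries carried the shift of small nucleolar RNA genes (63 of 67 lower, none higher, median −1.71), so a difference in RNA or library preparation could bear on this list, on protein synthesis genes and on the other hypoxia comparisons, and stays open. An effect of PPA2 loss and an effect of the hairpin apart from PPA2 also stay open, untested.

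The fall of HIF targets under normoxia held after the same correction (median −0.96) and in the 13 members above the list's median expression (median −0.99). A GC and length trend shared by all genes is therefore excluded as the only cause. RPKM is already scaled by library size, so the test on well-expressed members could hardly have shown an effect of depth and decides nothing. Estimated depths overlapped between groups, at 28004663 and 35722660 reads in control and 35735957 and 30725480 reads in knockdown libraries. An effect of PPA2 loss, an effect of the hairpin apart from PPA2 and other differences between the cultures stay open, untested.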

How the results depend on the processing

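Over the 365 genes and lists followed, 3387 values under other settings kept direction and side of the threshold, 189 lost their call, 6 gained one and 4 changed direction. With 1 library left out these counts were 1584, 102, 6 and 3, and the affected libraries stand beside each result. Losses under settings are named below. All lists lost their call with an estimated correlation, 0 passing under normoxia, under hypoxia and for the difference, at few residual degrees of freedom. The fry test, which also takes correlation from the data, passed 29 (normoxia), 36 (hypoxia) and 33 (difference) of 40 lists. It asks whether members change and does not set a list against other genes. With 34.2% to 58.4% of tested genes called, a pass there does not set a list apart. A fold of at least 2 left 188 (normoxia), 1037 (hypoxia) and 773 (difference) genes, an adjusted p under 0.01 left 2147 (normoxia) and 3635 (difference), and the normoxia count was 2349 with no filter on low values, where 34609 genes were tested. Leave-one-out counts under normoxia ran from 3027 to 4503, with fewer libraries, and the lone library was assumed to vary like the others. The correlation of both responses was 0.455 with a pseudocount of 0.1 and 0.444 to 0.466 with a library left out, and the HIF list's excess under hypoxia was 0.93 in control and 2.23 in knockdown cells; the cause was not tested.

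Of the 189 losses, 73 came with an estimated correlation, 38 with no filter on low values, 27 after quantile normalization, 21 under median-of-ratios scaling, 15 without mitochondrial genome genes, 6 in a fit of all 8 libraries, 4 with fry, 3 with a replicate block, 1 with a robust fit and 1 with a pseudocount of 0.01. Median-of-ratios scaling and quantile normalization both ended the calls of MT-ND5, DNAJB4, HMOX1, MRPS14, NDUFA5, NDUFB2, UQCR11 and RPA2 under normoxia, of PSME2, STAT2, BECN1 and SDF2L1 under hypoxia and of PFKM for the difference. Median-of-ratios scaling alone ended those of MT-ND1, DNAJA1, NCOA4, ATP5F1C, NDUFB9, ATIC and DUT (normoxia) and of cytosolic ribosomal proteins (difference). Quantile normalization alone ended those of CALR, ATF5, CCNE2, complex I and nucleotide synthesis (normoxia), of LDHB, PFKM, SLC2A1, ASCL2, IDI1 and MVD (hypoxia) and of HILPDA, LDHB and the mitochondrial mRNA list (difference), while MT-ATP6, MT-ATP8 and MT-CO3 passed under hypoxia. Without mitochondrial genome genes the calls of CALR and of NF-kB targets (normoxia), of PFKM, PSME2, STAT2, ASCL2, ATG16L1, BECN1, IDI1, MVD, SDF2L1, SOX9 and WNT targets (hypoxia) and of PFKM and cytosolic ribosomal proteins (difference) ended. With no filter those of PPA1, MIR635, CALR, CLPP, SUCLA2, NDUFV2, MT-ND1, MT-ND5, ERO1A, ATF5, DNAJA1, DNAJB4, HMOX1, NCOA4, PTGS2, ATP5F1C, MRPS14, NDUFA5, NDUFB2, NDUFB9, RRM2B, UQCR11, ATIC, CCNE2, DUT, RPA2 and CXCL3 (normoxia) and of MT-CO2, DNAJB11, RRM2B, SAMHD1, VLDLR, CD274, PSME2, STAT2, IDI1, MVD and SDF2L1 (hypoxia) ended. The other fits ended those of PRPS1, MRPS14, NDUFB2, CCNE2, RPA2, MT-ND1, complex I and nucleotide synthesis (normoxia), of SDF2L1, the endoplasmic reticulum list, cholesterol genes and WNT targets (hypoxia) and of cytosolic ribosomal proteins and WNT targets (difference). The cause was not tested.

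Values changed sign for CCN1 without mitochondrial genome genes (0.016), CCN2 without them (0.033), without control normoxia replicate 2 (0.080) and without knockdown normoxia replicate 2 (leave-one-out range −0.15 to 0.14), and MT-CO3 under median-of-ratios scaling (0.013) and without control hypoxia replicate 1 (leave-one-out range −0.20 to 0.074). The mitochondrial mRNA list under hypoxia turned to a lower direction after quantile normalization (median −0.36). The cause was not tested. With a replicate block the counts were 5060, 7751 and 5471 genes and 24, 22 and 25 lists for normoxia, hypoxia and the difference. The differences between replicates of control and knockdown correlated at 0.040 (normoxia) and −0.015 (hypoxia). Tests planned for counts were not run, since the tables hold no counts, and without counts the error from depth could not be separated from that between cultures.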

Other observations

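Some lists with several called members did not pass as lists. Their counts are to be read against all tested genes, of which 34.2% were called under normoxia and 58.4% under hypoxia. Under normoxia, targets of p53, the regulator of the DNA damage response, had 10 of 21 genes higher and 2 lower (the same adjusted over the list alone, median 0.16, camera adjusted p = 0.0758, and adjusted p = 0.409 with an estimated correlation). Under hypoxia, genes of mitochondrial fission and fusion had 8 of 15 lower and none higher (9 and 1 adjusted over the list alone, median −0.25, camera adjusted p = 0.234, and adjusted p = 0.475 with an estimated correlation). Genes of small RNA processing and sensing of double-stranded RNA had 7 of 14 higher and 3 lower (the same adjusted over the list alone, median 0.30, camera adjusted p = 0.151, and adjusted p = 0.569 with an estimated correlation). The same correction as in the results, for GC content and transcript length, moved the median of the fission and fusion genes from −0.25 to −0.080 and that of the small RNA genes from 0.30 to 0.18. NRF2 targets under hypoxia had 8 of 21 higher and 9 lower (8 and 11 adjusted over the list alone), with a median of −0.18, which a correction for GC content and transcript length turned positive (0.036), and a mean of 0.12 (camera adjusted p = 0.788, and adjusted p = 0.876 with an estimated correlation).

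Markers of other cell types were near absent. Of 14 fibroblast genes only ACTA2 reached a mean of 1, at 2.33 RPKM and 1.86 FPKM. Of 16 leukocyte genes CD14 was highest, at 1.17 RPKM and 0.479 FPKM, and of 10 endothelial and blood genes ESAM, at 2.0 RPKM and 1.69 FPKM, with CLDN5 also at a mean of at least 1 under normoxia.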
